A study of Mus musculus with 12 samples.

How the data were processed

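Gene expression was measured in 12 mouse skin cell samples from C57BL/6 mice, each hybridised to 1 one-colour (Cy3) Agilent microarray, so each of the 12 groups held 1 array. Per the labels' protocols, cells were sorted by flow cytometry into hair follicle stem cells (HFSCs, high for CD34 and ITGA6 and negative for SCA1), interfollicular epidermal cells (IFE, high for ITGA6 and SCA1) and total epidermal cells. Per the labels, young mice were 8 weeks old, aged mice at least 22 months, and the control and the Col17a1 conditional knockout (cKO, deletion from the K14 promoter) mice 12 weeks. Control and cKO mice had received 2 mg of tamoxifen on each of 5 days. Plucked HFSCs were taken 3 days after the hair had been pulled out by hand. Per the labels' protocols, total RNA was purified in nanogram amounts with an RNeasy micro kit, amplified with the Ovation Pico WTA system and labelled with a SureTag kit.

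The scanner values deposited by the authors are spot intensities on a linear scale, made per the file headers with Agilent Feature Extraction 10.7.3.1 under the protocol GE1_107_Sep09. Per the file headers, the processed intensity had a spatially detrended background subtracted, was detrended multiplicatively and had low signals replaced by surrogates. The flags deposited beside each spot, such as well above background, saturated or outlier, were set by the same software per the file headers. The mean spot intensity and the median intensity of the local background, also deposited by the authors, were used in 1 alternative only. The value table of the authors held log2 values for 55821 probes, of which 140 were controls. What the authors did to make that table was not given in the sources used here, so its scale, centring and direction were inferred from the values. Each probe had a median of 0 over the 12 columns, and each column followed the log2 processed intensity minus the array's 75th percentile and the probe's median, with r of at least 0.9999. The medians of the columns of the authors' table were 0.02 for young, -0.15 for young plucked, -0.01 for aged and 0.02 for aged plucked HFSCs. They were -0.02 for control, -0.2 for control plucked, 0.17 for cKO and -0.16 for cKO plucked HFSCs. They were -0.02 and 0.13 for young and aged total epidermis, and 0.08 and -0.01 for young and aged IFE.

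Here, control spots and outlier spots (129 to 269 per array) were left out, and no spot was saturated. The log2 processed intensity minus the array's 75th percentile was averaged over the spots of a probe. The 59305 spots per array other than controls belonged to 55681 probes, of which 28026 were matched by accession to a symbol in the RefSeq gene table of the mouse, and 27655 kept the name in the array files. They made up 34607 gene names, and 11284 of these had more than 1 probe. A gene was represented by its probe with the highest mean level over the 12 arrays. Coordinates are those of the array files, on mm9. No column of values from another series was present. No pair of arrays held the same values. Array number, not counting, limits the precision: between 49.71% and 64.97% of the spots of an array were well above background.

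Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg adjusted p under 0.05), with the package data.table, version 1.17.8; figures were drawn with matplotlib 3.10.9 in Python 3.11.15. A gene was tested when it was well above background on at least 2 arrays of the fit. With 1 array per group, the spread could come only from matched pairs in additive fits. Plucking, age, cKO and control against young were contrasts of 1 fit of mouse type (young, aged, control, cKO) and plucking over the 8 HFSC arrays, with 3 residual degrees of freedom. Aged and cKO cells together were set against their own controls with cohort and plucking as terms (4 degrees of freedom), and an interaction with plucking was fitted beside mouse type (2 degrees of freedom). IFE, total epidermis and HFSCs were compared over the 6 unplucked young and aged arrays with age as a term (2 degrees of freedom). The labels do not tell whether samples came from separate animals, nor whether plucked and unplucked cells shared one. The p-values of single genes then measure only the spread between these samples, which may be technical. Standard errors (SE) are the moderated ones of limma. Age in total epidermis and IFE was fitted beside population over these 4 arrays (1 degree of freedom). Comparisons of 1 array with 1 array have no test; genes were counted there when they were at least 2-fold apart (a log2 difference of 1) with the brighter array well above background.

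The 24 gene lists, with 367 genes, cover HFSC and bulge, hemidesmosome and basement membrane adhesion, epidermal differentiation, infundibulum and junctional zone, sebaceous gland, cell cycle, hair germ and anagen lineage, Wnt and hedgehog targets, BMP targets, p53 targets, DNA damage signalling and repair, senescence and secreted inflammatory factors, interferon response, extracellular proteases and inhibitors, immediate early and dissociation stress, wound and activated keratinocyte, T cells, Langerhans and myeloid cells, fibroblasts, endothelial cells, melanocytes, smooth muscle and pericytes, Merkel cells, and erythroid and skeletal muscle. 2 list genes (Serpina1b and Hspa1b) had no probe of that name. Lists were tested with camera of limma at a preset correlation between genes of 0.01, and again with an estimated correlation, adjusted over the lists of a contrast. At the preset correlation, camera sets the genes of a list against the other genes and treats them as nearly independent. Its p-value there does not measure the spread between samples. In single pairs, a list was held to its genes well above background on either array of the pair. Its median was placed among 10000 random lists of the same size matched on mean level. Sets of the 200 most HFSC-high and 200 most IFE-high genes were taken from the young and aged IFE and unplucked HFSC arrays. These arrays also enter the plucking, age and population comparisons, so the sets are not independent of these; the control and cKO arrays share none with the sets.

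Genes to be named were set by rule. For plucking and for the joint contrast of aged and cKO cells, they were the 10 largest rises and 10 largest falls past the threshold and in 1 direction in every pair. For aged, cKO and IFE comparisons they were 10 each way, filled up from genes not passing, ranked by the smaller of the differences of both pairs. Other contrasts took 5 each way by that rule, and single pairs of total epidermis and IFE the 5 largest each way. From each list came up to 4 members past the test, or up to 2 if none passed. Col17a1, Elane (neutrophil elastase) and the sorting markers Cd34, Itga6 and Ly6a (which encodes SCA1) were always included. Predicted genes and clones were not named, and 4 genes that the rule selects are not reported here. Where a gene was not well above background on any array of the dimmer side, the ratio is given as "at least N-fold". It sets the mean of the bright side against the mean of, per array, the higher of the lowest signal well above background and the gene's own signal. The groups, tests, lists, naming rule and most alternatives were set before the data were examined; the closing section names those added later. The alternatives were normexp background correction (offset 50) with quantile scaling, quantile scaling alone, the authors' value table, no filter and a strict filter on dim probes, the mean of a gene's probes, a fit of all 12 arrays, eBayes with trend and robust, and leaving out pairs or arrays. Sets of 100 and 400 genes were tried as well.

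The tests of 6 comparisons were tested on simulated data with 67, 67 and 66 genes changed by 2-, 8- and 32-fold. For plucking, over 25342 genes, 0%, 74.6% and 90.9% of them were recovered with 8 false calls. For aged against young, the shares were 0%, 22.4% and 87.9% with 5 false calls. For cKO against control, they were 0%, 16.4% and 77.3% with 2 false calls. For aged and cKO against their own controls, they were 0%, 53.7% and 92.4% with 5 false calls. For IFE against HFSC, over 23888 genes, they were 0%, 82.1% and 98.5% with 4 false calls. For the interaction, 0% were recovered at every fold, so a count of 0 genes says nothing there. Of 10 simulated lists of 37 genes shifted by 1 on the log2 scale, 10 were called in each of these 6 comparisons, and 0 of 10 without a shift. A simulated list was called at an unadjusted camera p under 0.05 with the preset correlation. Noise was drawn independently for each gene, so these lists cannot show how often lists of genes that vary together are called falsely.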

Results

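The 12 arrays covered HFSCs of young, aged, tamoxifen-treated control and Col17a1 cKO mice, each without plucking and 3 days after plucking, and total epidermis and IFE of young and aged mice. COL17A1 is a transmembrane collagen of the hemidesmosome, which anchors basal keratinocytes to the basement membrane. The series concerns hair follicle aging, and its design sets HFSCs of young, aged and cKO mice against each other. Among HFSC arrays, spots well above background made up 56.08% on the young, 61.45% on the aged, 59.97% on the control and 49.71% on the cKO array, and 62.67%, 59.18%, 64.23% and 61.34% on their plucked counterparts. They made up 64.97% and 56.39% in young and aged total epidermis, and 53.27% and 62.02% in young and aged IFE. The median correlation of an array with the other arrays was lowest for the unplucked control (0.868) and unplucked cKO (0.882) HFSC arrays and 0.883 to 0.908 on the others. Young and aged samples lay on slide 1, in slide row 1 and slide row 2, so age and slide row cannot be told apart. In both rows HFSCs lay in slide column 1, plucked HFSCs in column 2, total epidermis in column 3 and IFE in column 4. Population and slide column therefore cannot be told apart in the comparisons of IFE, total epidermis and HFSCs. Control and cKO samples lay on slide 2, so control against young cannot be told apart from the slide. Each group had 1 array, and n below counts pairs of arrays.

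Col17a1, the deleted gene, gave a bright signal on every array (1 probe, mm9 chromosome 19, 47720894 to 47720953). On the log2 scale relative to the array's 75th percentile, its level was 7.31 in control and 7.01 in cKO HFSCs without plucking, and 6.22 and 5.79 after it. The cKO against control difference was -0.37 ± 0.39 (SE, n = 2 pairs, adjusted p = 0.922), a ratio of 1.29. Whether the probe lies in the deleted part is not given by the labels, so its signal neither checks the genotype nor measures the deletion. Between aged and young HFSCs, Col17a1 differed by 0.01 ± 0.39 (SE, n = 2 pairs, adjusted p = 0.999): its level was 7.39 in young and 6.88 in aged cells without plucking, and 5.67 and 6.19 after it. Leaving out the plucked pair turned the sign, to -0.51. Elane, the neutrophil elastase gene, was well above background only on the aged HFSC (-2.77), control HFSC (-3.38) and aged IFE (-3.29) arrays. Of the sorting markers, the transcripts of Cd34 and Ly6a followed the sort. Cd34 stood between 5.62 and 6.69 in unplucked HFSCs and between 0.56 and 0.76 in total epidermis, and was at -3.05 in young IFE and not well above background in aged IFE. Ly6a stood between 3.33 and 4.37 in total epidermis and IFE, at 0.30 on the young HFSC array, and between -3.69 and -1.42 on the other HFSC arrays. Itga6, at the probe used, stood between 4.19 and 4.54 on the HFSC arrays. It was at 5.21 and 5.31 in young and aged total epidermis and at 5.75 and 5.77 in young and aged IFE. Its transcript was thus lower in HFSCs than in total epidermis, although the gate took HFSCs high for ITGA6.

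**Figure D1:**
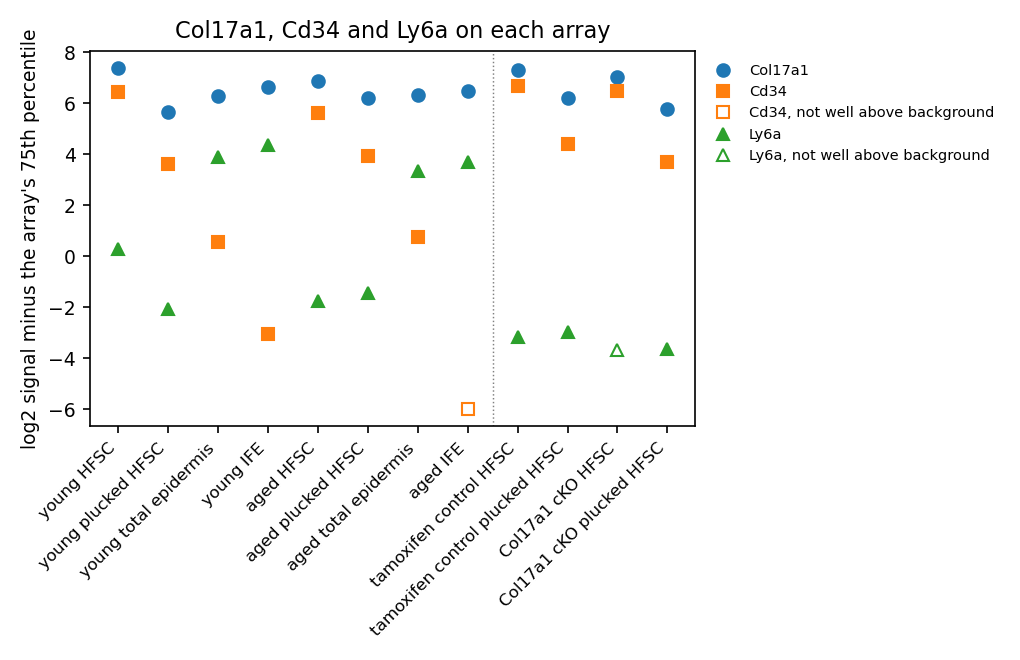
Levels of Col17a1, Cd34 and Ly6a (log2 signal minus the array's 75th percentile, vertical axis) on each of the 12 arrays, 1 point per array, with open symbols where the probe was not well above background and a dotted line between slide 1 and slide 2. Col17a1 lay between 5.67 and 7.39 on the 12 arrays, and Cd34 between 3.62 and 6.69 on the 8 HFSC arrays.

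Plucking tears out the hair shaft and starts a new growth phase of the follicle. 3 days later, HFSCs had higher levels of genes of cell division and of DNA repair and lower levels of bulge genes and BMP targets than unplucked HFSCs by camera at its preset correlation. With an estimated correlation, none of these 4 lists passed (adjusted p = 0.14, 0.14, 0.305 and 0.391), and 3 of 37, 2 of 19, 1 of 24 and 1 of 7 of their genes passed over all genes. Mki67, a marker of cycling cells, rose 14-fold (log2 change 3.81 ± 0.40, SE, n = 4 pairs, adjusted p = 0.0447), and Tpx2, a spindle assembly factor, rose 54.8-fold (5.78 ± 0.62). Id2, a BMP target, fell 7.04-fold (log2 change -2.82 ± 0.24, adjusted p = 0.0447), and Ccn2, known as Ctgf and a gene of the bulge list, fell 5.97-fold (-2.58 ± 0.29, adjusted p = 0.0481). Of 25342 genes tested, 100 rose and 27 fell (limma), all of them in 1 direction in every pair, and 4456 had an unadjusted p under 0.05.

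The largest rises were in genes that were dim without plucking. Pmch, the precursor of melanin-concentrating hormone, rose at least 32.1-fold (6.33 ± 0.70), St8sia2, a polysialyltransferase, at least 27.1-fold (5.86 ± 0.45), Neil3, a DNA glycosylase, at least 24.5-fold (5.85 ± 0.50) and Parpbp, a PARP1-binding protein, at least 29.7-fold (5.71 ± 0.57). Pla2g7, a secreted phospholipase, rose 72-fold (6.17 ± 0.40), Col27a1, a fibrillar collagen, 54.1-fold (5.76 ± 0.54) and Iqgap3, a scaffold protein, 52.8-fold (5.72 ± 0.35), each with 1 of 4 unplucked arrays well above background. Spc24, a kinetochore subunit, rose 65.4-fold (6.03 ± 0.50) and Brip1, a helicase bound to BRCA1, 51.1-fold (5.68 ± 0.45), with 2 of 4 unplucked arrays well above background, as for Tpx2. Among the largest falls, Adra2a, an adrenergic receptor, fell 17.6-fold (-4.14 ± 0.26, adjusted p = 0.0394), Aspn, a small leucine-rich proteoglycan, 16.9-fold (-4.08 ± 0.39), Myoc, which encodes myocilin, 16.3-fold (-4.03 ± 0.46) and Camk2n1, an inhibitor of CaM kinase II, 15.1-fold (-3.92 ± 0.29). Pdzrn4 fell 14-fold (-3.81 ± 0.41) and Col8a2, a short-chain collagen, 11-fold (-3.46 ± 0.35). Fzd9, a Wnt receptor, fell 27.3-fold (-4.77 ± 0.54), Ngef 24.6-fold (-4.62 ± 0.33), Grik1, a glutamate receptor, 20.2-fold (-4.33 ± 0.33) and Galnt15, a glycosyltransferase, 18.1-fold (-4.18 ± 0.35), each with 1 or 2 of 4 plucked arrays well above background. The adjusted p of these 20 genes lay between 0.0394 and 0.0493.

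Of the 37 cell cycle genes, 3 rose past the threshold over all genes (Tpx2, Mki67 and Bub1, a spindle checkpoint kinase, 44.1-fold, 5.46 ± 0.57, with 1 of 4 unplucked arrays well above background) and 34 did not pass. Adjusted over the list alone, 34 rose and 0 fell, and the median log2 change was 2.90 (camera adjusted p = 1.86e-26; adjusted p = 0.14 with an estimated correlation). In the DNA damage and repair list (19 genes, median 1.23), 2 genes rose, among them Brca1 at least 5.7-fold (4.04 ± 0.40, adjusted p = 0.0447), 17 did not pass, and 9 rose and 0 fell adjusted over the list alone (adjusted p = 2.48e-08; adjusted p = 0.14 with an estimated correlation). Of 24 HFSC and bulge genes, Ccn2 fell and 23 did not pass; adjusted over the list alone, 13 fell and 0 rose, with a median of -0.89 (adjusted p = 8.4e-06; adjusted p = 0.305 with an estimated correlation). Among its members, the transcription factors Sox9, Lhx2 and Tbx1 stood at -0.10, -0.17 and 0.04, and Lgr5 at -0.33 (adjusted p = 0.525). Its other transcription factors, Nfatc1, Foxc1, Tcf7l1 and Tcf7l2, are not given here, so these values do not stand for the class. Cd34 was at -2.40 ± 0.30 (adjusted p = 0.0558) and lower in 4 of 4 pairs. Of 7 BMP targets, Id2 fell and 6 did not pass; adjusted over the list alone, 6 fell and 0 rose, with a median of -2.04 (adjusted p = 2.17e-05; adjusted p = 0.391 with an estimated correlation). Id1 was at -2.04 (adjusted p = 0.0505). Col17a1 was lower in 4 of 4 pairs, at -1.18 ± 0.27 (adjusted p = 0.133). Mitf, the master regulator of melanocytes, fell 7.18-fold (-2.84 ± 0.23, adjusted p = 0.0438), alone among 6 melanocyte genes (list median 0.53, adjusted p = 0.933), and was the 1 gene that fell there adjusted over the list alone.

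**Figure D2:**
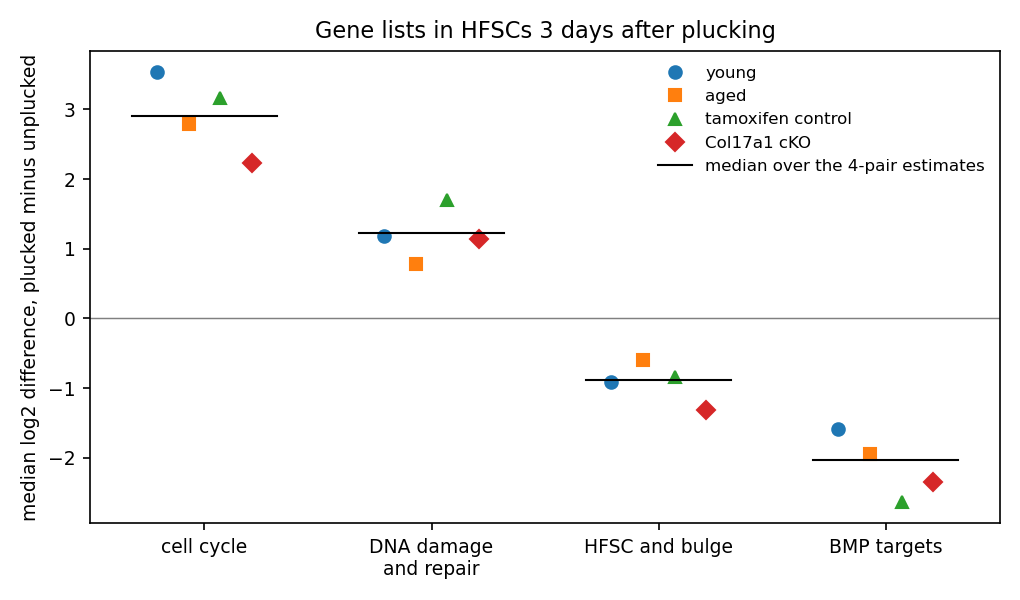
Median log2 difference between plucked and unplucked HFSCs (vertical axis) of 4 gene lists, with 1 symbol per mouse type and a black line for the median over the 4-pair estimates. The cell cycle medians were 3.54 in young, 2.79 in aged, 3.17 in control and 2.24 in cKO mice, and all BMP target medians lay between -2.63 and -1.59.

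The other lists did not pass camera, with 0 members past the threshold over all genes apart from Mitf. The infundibulum and junctional zone list was closest (11 genes, median 0.64, adjusted p = 0.0676, 3 rose and 0 fell adjusted over the list alone). Immediate early and dissociation stress genes had a median of -0.60 (18 genes, adjusted p = 0.113, 1 rose and 5 fell adjusted over the list alone). Proteases and inhibitors (15 genes) stood at -0.29 (adjusted p = 0.207, 1 rose and 3 fell adjusted over the list alone), fibroblast markers (6 genes) at -0.72 (adjusted p = 0.207, 1 rose and 3 fell) and senescence and secreted factors (10 genes) at 0.49 (adjusted p = 0.777, 2 rose and 2 fell). Epidermal differentiation genes (27 genes) had a median of 0.09 (adjusted p = 0.777, 2 rose and 2 fell), hair germ and anagen genes (19 genes) -0.17 (adjusted p = 0.876, 2 rose and 1 fell) and Wnt and hedgehog targets (14 genes) 0.33 (adjusted p = 0.38, 2 rose and 1 fell), again adjusted over the list alone. In the remaining lists 0 genes passed adjusted over the list alone. Their medians were -0.08 for hemidesmosome genes (adjusted p = 0.574), 0.47 for sebaceous gland (adjusted p = 0.207), 0.20 for p53 targets (adjusted p = 0.207), -0.81 for interferon response (adjusted p = 0.332) and 0.65 for wound genes (adjusted p = 0.574). Markers of other cells stood at -0.28 for T cells (adjusted p = 0.38), -0.21 for Langerhans and myeloid cells (adjusted p = 0.777), 0.00 for endothelial cells (adjusted p = 0.846), 0.23 for smooth muscle and pericytes (adjusted p = 0.482), -0.29 for erythroid and muscle genes (adjusted p = 0.802) and 0.28 for the 2 Merkel cell genes, too few for camera. Of the 130 IFE-high genes tested, 3 rose and 0 fell, and 17 rose and 1 fell adjusted over the list alone (median 0.64, or 0.52 with dim genes at their bounds; adjusted p = 5.07e-07; adjusted p = 0.0269 with an estimated correlation). Of 200 HFSC-high genes, 1 rose and 15 fell, and 12 rose and 75 fell adjusted over the list alone (median -1.06, or -0.99 at the bounds; adjusted p = 1.24e-10; adjusted p = 0.0532 with an estimated correlation). Both sets were chosen partly on the unplucked arrays used here, so neither is independent evidence of its direction.

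The medians of the 4 lists had the same sign on both slides. With an estimated correlation, no list passed within a slide (adjusted p = 0.808 for these 4 on slide 1 and 0.822 on slide 2). Each fit had 4 arrays and 1 residual degree of freedom. On slide 1, 0 of 22893 genes passed (limma) and 2702 had an unadjusted p under 0.05; on slide 2, it was 0 of 23432 and 2893. The cell cycle median was 3.18 on slide 1 (adjusted p = 1.64e-32) and 2.80 on slide 2 (adjusted p = 8.9e-18), and that of DNA damage and repair 1.13 (adjusted p = 1.85e-07) and 1.35 (adjusted p = 1.83e-06). HFSC and bulge genes stood at -0.58 (adjusted p = 1.59e-05) and -0.97 (adjusted p = 0.00012), and BMP targets at -1.83 (adjusted p = 9.62e-05) and -2.42 (adjusted p = 0.000252). Fibroblast markers were at -1.37 on slide 1 (adjusted p = 0.00578) and -0.55 on slide 2 (adjusted p = 0.675), while immediate early genes were at -0.17 (adjusted p = 0.981) and -0.92 (adjusted p = 0.0025), and p53 targets at 0.28 (adjusted p = 0.546) and 0.34 (adjusted p = 0.035). These 3 lists had an adjusted p of 0.808 to 0.994 with an estimated correlation. Without the young, the aged, the control or the cKO pair, 0 genes passed. The same held without the unplucked control and cKO arrays, those with the lowest median correlations with the rest (0.868 and 0.882), a choice made after the data were seen. With normexp correction and quantile scaling 725 rose and 396 fell, so that rises made up 64.7% of the calls in place of 78.7%.

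Aged and young HFSCs were compared to find how the transcripts of these cells differ with age. No gene passed: 0 of 25342 (limma, smallest adjusted p = 0.242), with 1231 at an unadjusted p under 0.05. Cell cycle genes, the list with the smallest p, stood lower in aged cells, with 20 of 37 lower and 0 higher in both the unplucked and the plucked pair (median -0.41, adjusted p = 0.0164; adjusted p = 0.623 with an estimated correlation). 0 of its genes passed over all genes and 0 adjusted over the list alone. Fibroblast markers were lower as well (6 genes, median -0.47, adjusted p = 0.0477; adjusted p = 0.623 with an estimated correlation), and 1 fell adjusted over the list alone, Dcn, which encodes the proteoglycan decorin (at least 2.78-fold, adjusted p = 0.929 over all genes), which was well above background on 1 of these 4 arrays. Among proteases and inhibitors 2 rose adjusted over the list alone, both serine proteases of neutrophil granules, Elane (2.76 ± 0.36, adjusted p = 0.627 over all genes) and Ctsg. Elane was well above background on 1 of 2 aged arrays and on neither young array, at least 1.87-fold apart, and Ctsg on 1 of 2 aged arrays and on neither young array.

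Genes far apart in both pairs did not pass, and most were not well above background on the dimmer side. Chst9, a sulfotransferase, was at least 14.7-fold higher in aged cells (5.77 ± 1.10, SE, n = 2 pairs), Bdh2, a dehydrogenase, 11.5-fold, Sfrp2, a secreted Wnt antagonist, 11.2-fold and Avpr1a, a vasopressin receptor, 11-fold, each as a lower bound. The bounds for Tex43, Tcaf3, Hormad1, Ceacam12 and Fank1 lay between 3.07 and 9.43. Lower in aged cells were Cyp2g1, a cytochrome P450, at least 9.99-fold (-4.05 ± 0.62), Ikzf4, an Ikaros family factor, at least 6.11-fold, and Zfp239 at least 4.61-fold. Tnfrsf25, Vmn2r67, Tube1, Bcl2l14, Zfp69 and Nexmif were at least 2.6- to 3.54-fold lower. The adjusted p of these genes lay between 0.456 and 0.93. Cyp2g1, Ikzf4, Zfp239, Vmn2r67, Bcl2l14 and Nexmif were well above background on neither control HFSC array, so the young arrays stood apart there. Tnfrsf25 was so on the unplucked control array only, and Tube1 and Zfp69 on the plucked one only. Of the higher genes, Sfrp2 and Tcaf3 were well above background on both control arrays. Bdh2 and Ceacam12 were so on the plucked one only, and the others on neither. In single pairs, 4419 genes were at least 2-fold higher and 2744 lower in aged cells without plucking, and 2384 and 2419 after it. The share of genes in the same direction in both pairs was 55.8%, against 50% by chance, with r = 0.092 across genes, which are not independent replicates. The interferon list stood at -0.23 (adjusted p = 0.055), immediate early genes at 0.37 with 10 of 18 higher in both pairs (adjusted p = 0.0729) and hemidesmosome genes at -0.18 (adjusted p = 0.105).

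The cell cycle difference differed between the pairs. After plucking, 35 of 37 cell cycle genes were lower in aged than in young HFSCs (median -0.67, below all of 10000 random lists), whereas without plucking the median was 0.02 (percentile 41.58). The unplucked median covers fewer than the 37 genes, because members such as Bub1, Kif11 and Top2a were well above background on neither array and were left out. In total epidermis 31 of 34 were higher in aged cells (median 0.56), and in IFE 34 of 35 (median 0.59), both above all random lists. In cKO against control HFSCs the median was 0.96 without plucking and -0.07 after it (percentile 20.44). Each of these values compares single arrays and has no test of its own. After plucking, all 9 wound genes were higher in aged cells (median 1.27, percentile 100), and interferon genes stood lower (-1.58, percentile 0.14); without plucking, wound genes (-1.18, percentile 0.02) and hemidesmosome genes (-0.51, 19 of 22 lower, percentile 1.04) were lower.

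**Figure D3:**
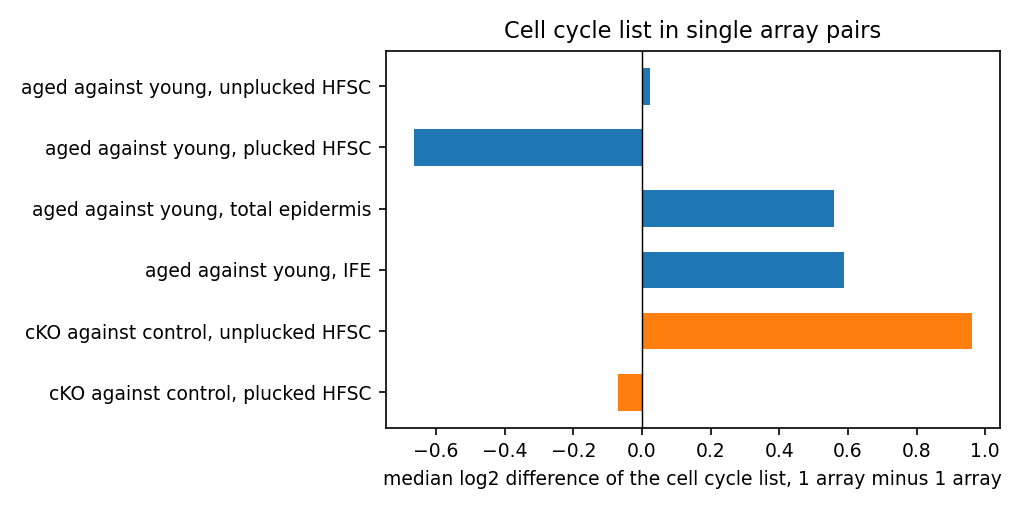
Median log2 difference of the cell cycle list (horizontal axis) between single arrays, aged against young in blue and cKO against control in orange, 1 bar per pair and no error bars because each pair has 1 array per side. The median was -0.67 in plucked HFSCs of aged against young mice and 0.56 and 0.59 in total epidermis and IFE.

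HFSCs of Col17a1 cKO mice were compared with those of tamoxifen-treated controls. BMP targets stood lower in cKO cells: 6 of 7 were lower in both pairs (median -0.82, adjusted p = 0.00583; adjusted p = 0.96 with an estimated correlation). Their medians were -0.63 without and -0.89 after plucking, and Atoh8 was at -2.06 (adjusted p = 0.74) and Id3 at -1.88 (adjusted p = 0.636), so 0 of them passed over all genes and 0 adjusted over the list alone. No gene passed: 0 of 25342 (limma, smallest adjusted p = 0.128), with 1640 at an unadjusted p under 0.05; a fit of all 12 arrays called 3. Without the filter on dim probes the BMP list no longer passed. In the interferon list 1 gene rose adjusted over the list alone, Gbp2, a guanylate-binding GTPase (at least 9.53-fold, adjusted p = 0.41 over all genes), and 1 fell, Usp18, which removes ISG15 (at least 1.32-fold, adjusted p = 0.629).

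Sycp1, of the synaptonemal complex, was at least 19-fold higher in cKO cells (5.70 ± 0.35, SE, n = 2 pairs, adjusted p = 0.128) and Esr1, the estrogen receptor, at least 16.4-fold (5.57 ± 0.77, adjusted p = 0.41). Nnat, an imprinted gene, was at least 39.5-fold higher at the probe used, while another of its probes was above background in control cells. Gypc, a membrane glycoprotein of red cells, was 52.3-fold higher with 1 of 2 control arrays well above background. The bounds were 18.2-fold for Vit, 13.1-fold for Dnajb13, 12-fold for Map3k7cl, 11.5-fold for Kiss1r, the kisspeptin receptor, 7.09-fold for Tsga10ip and 6.89-fold for Defb20. Vit was also well above background on every young and aged HFSC array, and Nnat on all of these but the young plucked one. For these genes the control arrays stood apart. Sycp1, Gypc, Map3k7cl, Tsga10ip and Defb20 were well above background on no young or aged HFSC array, and Esr1, Dnajb13 and Kiss1r on some. Lower in cKO cells were Rasl11b (at least 17.7-fold, -5.07 ± 0.90), Sfrp2 (at least 8.57-fold, -5.17 ± 1.18), Lpin1, a phosphatidate phosphatase (at least 7.89-fold), Zfp719 (at least 7.22-fold), Senp6 (at least 4.97-fold), Dock8 (at least 4.29-fold) and Tfr2, a transferrin receptor (at least 4.15-fold). With 1 of 2 cKO arrays well above background, Ifi202b was 30.2-fold, Trpv3, an ion channel of keratinocytes, 18.1-fold and Smim24 9.32-fold lower. Of these lower genes, Tfr2 was well above background on no young or aged HFSC array. Sfrp2 and Lpin1 were so on the aged ones only, Trpv3 on the plucked ones only, and the others on all. The adjusted p of these 20 genes lay between 0.128 and 0.754. Directions in the unplucked and plucked pairs were the same for 49.7% of genes (r = 0.007). In single pairs 4237 genes were at least 2-fold higher and 4996 lower in cKO cells without plucking, and 2870 and 3008 after it. Without plucking the larger side turned with normexp correction (2304 and 1921), without a filter (9041 and 5456) and with the strict filter (2821 and 2160). The HFSC-high (median -0.08) and IFE-high (median -0.14) genes did not pass (adjusted p = 0.894 for both), and their means and test directions had the other sign than the medians. The IFE-high median turned to 0.10 without the filter and to 0.07 and 0.12 with sets of 100 and 400 genes, and the HFSC-high median to 0.01 with sets of 100. Without plucking, 20 of 25 epidermal differentiation genes were lower in cKO cells (median -1.04, below all random lists).

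Control and young HFSCs are both wild type and served as a yardstick. They differ in age by weeks, tamoxifen and slide. 0 of 25342 genes passed (limma, smallest adjusted p = 0.207), with 2218 at an unadjusted p under 0.05, and no list passed (smallest adjusted p = 0.657). Sfrp2 was at least 10.9-fold higher in control cells (5.49 ± 1.18, SE, n = 2 pairs), Epm2a, a glycogen phosphatase, 17.7-fold with 1 of 2 young arrays above background, Ifitm5 11.2-fold likewise, Olfml1 at least 3.68-fold and Ccdc110 at least 3.44-fold. Cyp2g1 was at least 22.2-fold lower (-6.01 ± 0.62), Elovl3, a fatty acid elongase of sebaceous glands, 17.4-fold, Ikzf4 13.6-fold (another of its probes was above background in control cells), Zfp239 10.2-fold and S100a9, a calgranulin, 7.85-fold, each as a lower bound. The adjusted p of these 10 lay between 0.526 and 0.581. Ly6a stood at -2.18 ± 0.75 (adjusted p = 0.569). Directions were the same in both pairs for 59.3% of genes (r = 0.167), a larger share than in either comparison above.

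Aged and cKO HFSCs were set together against their own controls to find what they share. BMP targets stood lower, with 5 of 7 lower in all 4 pairs (median -0.54, adjusted p = 0.0416; adjusted p = 0.714 with an estimated correlation). For aged and cKO against their own controls, the call was lost without a filter on dim probes (adjusted p = 0.0867) and with quantile scaling (adjusted p = 0.0617), with 0 of the genes past the threshold over all genes and 0 adjusted over the list alone. 0 of 25342 genes passed (limma, smallest adjusted p = 0.792), 1490 had an unadjusted p under 0.05, and a fit of all 12 arrays called 3. Adjusted over the list alone, Gata6, a factor of the upper follicle, rose (1.92 ± 0.39, SE, n = 4 pairs, with 3 of 4 arrays of the dimmer side well above background), Junb, an immediate early factor, rose (1.31 ± 0.25) and Usp18 fell (at least 1.48-fold), each with an adjusted p of 0.792 over all genes. Across genes, the aged and cKO differences had r = -0.011 without plucking and r = 0.02 after it. Without plucking, 678 genes were at least 2-fold higher in both, against 604 for independent lists, 600 were lower in both, against 452.6, and 1422 went opposite ways, against 1091.2. After plucking, these were 382 against 219.6, 380 against 238.7 and 716 against 457.9. In plucked aged against young HFSCs, on arrays not used to choose the sets, HFSC-high genes had a median of 0.01 (percentile 61.04) and IFE-high genes -0.19 (percentile 0.4). Cd34 stood at -0.37 ± 0.28 (adjusted p = 0.804) and Col17a1 at -0.18 ± 0.26 (adjusted p = 0.874) in aged and cKO cells together.

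The plucking response of aged and cKO cells was compared with that of young and control cells. Cell cycle genes rose less in aged and cKO cells (37 genes, median difference -0.87, 21 lower and 4 higher in both, adjusted p = 0.00169; adjusted p = 0.984 with an estimated correlation). Epidermal differentiation genes (27 genes, 0.60, 14 higher and 4 lower in both, adjusted p = 0.0342) and wound genes (8 genes, 1.99, 6 higher and 1, Ereg, lower in both, adjusted p = 0.0382) stood higher. Both had an adjusted p = 0.984 with an estimated correlation. No gene passed, 0 of 25342 (limma, smallest adjusted p = 1), with 1137 at an unadjusted p under 0.05, and 0 genes of these 3 lists passed adjusted over the list alone. The rule selected Epm2a, Comtd1, Xkr8, Nxph3 and Kdelr3 upward and Cfap69, Galm, Tbkbp1, Cep97 and Serpinb9 downward, all with an adjusted p of 1. Nxph3 (4.76 ± 0.58) was well above background on all 8 HFSC arrays. The other 9 were not on 2 to 5 of the 8, so the size of their differences is not given.

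IFE and HFSC arrays were compared to define the populations. The bulge genes Tbx1, Lgr5 and Lhx2 were far lower in IFE: Tbx1, a transcription factor, by at least 1010-fold (-10.23 ± 0.33, SE, n = 2 pairs, adjusted p = 0.00926), Lgr5, an R-spondin receptor, by at least 285-fold (-9.95 ± 0.47) and Lhx2, a LIM homeodomain factor, 317-fold (-8.31 ± 0.44). Bmp4, a secreted BMP ligand, was 44.6-fold higher in IFE (5.48 ± 0.27), and the suprabasal keratin Krt1 4.35-fold (2.12 ± 0.29, adjusted p = 0.0335), while other genes of the epidermal differentiation list fell. Of 23888 genes, 502 were higher and 633 lower in IFE (limma). Leaving out single arrays gave 318 (without the aged IFE array), 350 (young IFE), 540 (aged total epidermis) and 642 (young total epidermis) genes, and 794 and 849 without the young or the aged HFSC array, where the larger side turned (451 higher and 343 lower, and 498 and 351). The sorting markers Cd34 (1500-fold lower, with 1 of 2 IFE arrays well above background) and Ly6a (4.76 ± 0.47) differ by choice of the gate; Itga6 was at 1.25 (adjusted p = 0.0823) and Col17a1 at -0.58 ± 0.29 (adjusted p = 0.361).

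Among the genes furthest apart, Col8a2 was at least 267-fold, Grem1, a BMP antagonist, 742-fold, Adra2a 225-fold, Eya2 207-fold, Serpinb11 184-fold and Camk4, a calmodulin kinase, 182-fold lower in IFE, each as a lower bound. Higher in IFE were Cpxm2 (at least 87.2-fold), Olfr686 (66.1-fold), Olfr599 (59.3-fold), Sox6 (46-fold), Mirt2 (36.9-fold), Il2rg (30.6-fold), Olfr715 (30.1-fold), Vmn2r99 (24.9-fold) and Mab21l4 (20-fold), each as a lower bound, and Tox3 59.3-fold. Il2rg encodes the common cytokine receptor chain, and Olfr686, Olfr599, Olfr715 and Vmn2r99 belong to olfactory and vomeronasal receptor families by the names of their probes, 1 each, whose match to other transcripts was not checked. Of 24 HFSC and bulge genes 20 fell, 0 rose and 4 did not pass, and 22 fell adjusted over the list alone (median -5.89, or -5.56 at the bounds; adjusted p = 5.46e-27; adjusted p = 0.439 with an estimated correlation). Of 7 BMP targets 5 fell, Id2 by 15.6-fold and Smad7, an inhibitory Smad, by at least 16.5-fold, and 7 adjusted over the list alone (median -2.92, or -2.65 at the bounds; adjusted p = 7.33e-08; adjusted p = 0.439 with an estimated correlation). Of 5 fibroblast markers 4 fell, among them Col6a1 (-5.33, with 1 of 2 IFE arrays well above background) and Col1a2 (-4.69), and 5 adjusted over the list alone (median -4.48; adjusted p = 3.55e-06; adjusted p = 0.439 with an estimated correlation). Of 34 cell cycle genes 3 rose, E2f1 by 5-fold, Kif23 by at least 5.25-fold and Bub1b by at least 2.58-fold, and 7 adjusted over the list alone (median 1.38; adjusted p = 1.65e-07; adjusted p = 0.517 with an estimated correlation). Of 18 immediate early genes, which tissue dissociation is known to raise, 5 rose, Fosb by 16.1-fold and Fos by 13.7-fold among them, and 9 rose and 1 fell adjusted over the list alone (median 1.07; adjusted p = 0.00114; adjusted p = 0.439 with an estimated correlation). Of 9 wound genes Krt6a, a keratin of the follicle's companion layer, fell at least 74.1-fold and Krt6b fell (-2.76), while 1 rose and 3 fell adjusted over the list alone (median -1.55, or -1.14 at the bounds; adjusted p = 0.0114; adjusted p = 0.439 with an estimated correlation). Of 11 infundibulum genes Krt17 fell 6-fold, and the median was -0.24 (adjusted p = 0.0469; adjusted p = 0.539 with an estimated correlation).

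Other lists held genes that moved both ways. In hair germ and anagen genes (16 genes, median -0.43, adjusted p = 0.667) Bmp4 and Cux1 (20-fold, with 1 of 2 HFSC arrays well above background) were among 3 that rose, and Hoxc13 (at least 15-fold) and Runx1 (at least 12.8-fold) among 3 that fell. In Wnt and hedgehog targets (14 genes, 0.13, adjusted p = 0.865) Gli1, a hedgehog effector, fell at least 40.4-fold and Hhip at least 5.15-fold, and Apcdd1, a Wnt inhibitor, rose 9.69-fold. In epidermal differentiation (27 genes, -0.90, adjusted p = 0.17) 2 rose and 3 fell, with Calml3 51-fold and Sprr1b at least 8.58-fold lower, and 5 rose and 6 fell adjusted over the list alone. Igfbp5 (at least 52.4-fold) and Igfbp7 (-1.92) fell in the senescence list, Timp2, a metalloprotease inhibitor, fell 102-fold, Egfl6, a basement membrane protein, fell 10.9-fold, and Mitf fell (-3.51) while Pmel, a melanosome protein, rose (2.62). Sesn1 (-1.76) and Sesn2 (1.69) were the p53 targets that passed. The HFSC-high and IFE-high sets were defined by this comparison.

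Immune cell genes stood higher in total epidermis than in sorted HFSCs, where several of them, such as Cd3e, Ptprc and Cd68, were well above background on all 8 HFSC arrays. Of 9 T cell genes 3 rose, the T cell receptor chain Cd3g at least 17.5-fold (5.93 ± 0.27, SE, n = 2 pairs, adjusted p = 0.0193), Trat1 at least 10.6-fold and Cd3e 7.23-fold, and 8 rose adjusted over the list alone (median 2.85, adjusted p = 6.6e-07; adjusted p = 0.401 with an estimated correlation). Of 10 Langerhans and myeloid genes the signalling adaptors Tyrobp (at least 22-fold) and Fcer1g (7.67-fold) rose, and 8 adjusted over the list alone (median 2.74, adjusted p = 1.57e-05; adjusted p = 0.51 with an estimated correlation). Of 24 HFSC and bulge genes 15 fell, and 23 adjusted over the list alone (median -4.19, or -3.91 at the bounds; adjusted p = 8.04e-22; adjusted p = 0.401 with an estimated correlation), with Ccn2 at -6.21, Krt24 at -5.62 and Wif1, a Wnt inhibitor, at least 28.5-fold lower. In all, 450 of 23888 genes were higher and 483 lower (limma), and 455 and 232 without the aged HFSC array. Without the young HFSC, the young total epidermis or the aged total epidermis array, 0 passed.

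Il2rg (at least 38.1-fold), Cpxm2 (56-fold), Sox6 (26.9-fold) and Pglyrp4, a peptidoglycan recognition protein (15.3-fold), were also highest against HFSCs, and Camk4 (at least 183-fold), Gfra2 (99.8-fold), Pcolce2 (54.8-fold) and Scrg1 (39.3-fold) lowest, each as a lower bound, with Sgcd, a sarcoglycan, 111-fold lower and 1 of 2 total epidermis arrays well above background. Of 7 BMP targets 5 fell, and 6 adjusted over the list alone (median -3.29, or -3.16 at the bounds; adjusted p = 1.92e-07; adjusted p = 0.401 with an estimated correlation). Of 5 fibroblast genes 4 fell (median -3.77; adjusted p = 0.000177; adjusted p = 0.51 with an estimated correlation). Hemidesmosome genes fell in 2 of 21, Egfl6 (-4.18) and Col4a1 (-2.67, with 1 of 2 total epidermis arrays well above background) (median -0.58; adjusted p = 0.000134; adjusted p = 0.569 with an estimated correlation), and wound genes in 2 of 9 (median -1.88, or -1.11 at the bounds; adjusted p = 0.00462; adjusted p = 0.401 with an estimated correlation). Cell cycle genes rose in 2 of 34, Aurka (2.27) and Bub1b (at least 1.55-fold) (median 0.89, or 0.77 at the bounds; adjusted p = 6.1e-05; adjusted p = 0.537 with an estimated correlation), and immediate early genes in 4 of 18, with Egr2 at 2.84 (median 0.99; adjusted p = 0.00136; adjusted p = 0.401 with an estimated correlation). Dsg1a, a desmosomal cadherin (3.14), Casp14 (2.40), Cst6 (2.34), Cdkn1a (2.38) and Cdkn2b (2.83, with 1 of 2 HFSC arrays well above background) rose, whereas Sprr1b (at least 12.2-fold, adjusted p = 0.0193), Calml3 (-2.74, adjusted p = 0.0242), Timp2 (-4.05, adjusted p = 0.0353) and Mitf (-3.17, adjusted p = 0.0203) fell. Among melanocyte genes Pmel rose (2.46, adjusted p = 0.037).

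Against IFE, total epidermis had 0 rises and 3 falls (limma), with 971 genes at an unadjusted p under 0.05, and 0 genes passed without any one of the 6 arrays or with the authors' value table. Olfr686 was the 1 named gene past the threshold, at least 100-fold lower (-8.01 ± 0.36, SE, n = 2 pairs, adjusted p = 0.0499), and Olfr599 (at least 89.7-fold), Mirt2 (at least 55.8-fold), Olfr715 (at least 45.6-fold) and Atp8b5 (61.9-fold, with 1 of 2 total epidermis arrays well above background) did not pass. Ctla2a (51.6-fold), Tbx1 (34.5-fold), Eya2 (16.3-fold), Fgf18 (13.2-fold) and Trat1 (11.3-fold), each as a lower bound, stood highest in total epidermis without passing. 7 of 9 T cell genes rose adjusted over the list alone (median 2.83, adjusted p = 1.3e-17; adjusted p = 0.27 with an estimated correlation), 10 of 24 HFSC and bulge genes (1.15, adjusted p = 6e-17; adjusted p = 0.27 with an estimated correlation), 6 of 11 infundibulum genes (2.22, adjusted p = 1.31e-10; adjusted p = 0.27 with an estimated correlation), 8 of 10 Langerhans and myeloid genes (2.23, or 1.91 at the bounds, adjusted p = 5.19e-11; adjusted p = 0.459 with an estimated correlation) and 2 of 27 epidermal differentiation genes (1.07, adjusted p = 2.78e-13; adjusted p = 0.459 with an estimated correlation). None of these members passed over all genes. Sebaceous (0.60, adjusted p = 0.00235) and fibroblast genes (0.72, adjusted p = 0.0412) stood higher and hemidesmosome (-0.39, adjusted p = 6.8e-05) and cell cycle genes (-0.39, adjusted p = 0.00091) lower, all with an adjusted p = 0.654 with an estimated correlation. The median, mean and test of a list were of 1 sign in all 36 of the 207 tested combinations of a list with a comparison that passed, and not in 37 others.

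Between aged and young total epidermis, single arrays differed at least 2-fold in 1261 genes that were higher and 1667 lower with age, and in 799 and 527 with the strict filter. All 10 Langerhans and myeloid genes (median 1.00) and 8 of 9 T cell genes (0.60, percentile 99.79) were higher on the aged array. Of 26 epidermal differentiation genes 22 were lower (-0.99), and of 14 sebaceous gland genes 13 (-1.24), both below all random lists. Olfr50 was at least 63.6-fold, Henmt1, a small RNA methyltransferase, 37.2-fold, Mmp1a, a collagenase, 32.9-fold, Ceacam14 25.2-fold and Btnl6 21.6-fold higher, and Hottip, a long noncoding RNA, 201-fold, Rab9b 126-fold, Xkr6 119-fold, Vmo1 109-fold and Olfr507 101-fold lower, each as a lower bound. In IFE, 1985 genes were higher and 821 lower on the aged array. Higher were Tmprss11f, a serine protease (at least 25-fold), Ucn3 (23.8-fold), Il25, a cytokine (at least 10.8-fold), Sorbs2os (at least 9.43-fold) and Clec5a (at least 7.54-fold). Lower were Efcab3 (49.1-fold), Klra1 (27.3-fold), Osr1 (24.6-fold) and Aldoart1 (24.6-fold), each as a lower bound. The higher genes made up 70.7% of the IFE differences, and 57.8% with quantile scaling. With both pairs in a fit of population and age over these 4 arrays, added after the data were seen, 0 of 22760 genes passed (limma, smallest adjusted p = 0.587), with 1484 at an unadjusted p under 0.05. Cell cycle genes stood higher in that fit (median 0.53, adjusted p = 3.5e-10), as did immediate early (0.29, adjusted p = 0.0238) and T cell genes (0.54, adjusted p = 0.0286). Epidermal differentiation (-0.49, adjusted p = 0.000614) and sebaceous gland genes (-0.57, adjusted p = 0.0059) stood lower, and these 5 lists had an adjusted p = 0.94 with an estimated correlation. 0 of their genes passed adjusted over the list alone. Langerhans and myeloid genes did not pass (0.22, adjusted p = 0.354). Age is confounded with slide row in this fit.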

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

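Among the tests in this part, the splits within mouse types, the contrast of the aged effect with the cKO effect, the test of a lower yield of the unplucked arrays and the test of slide row were chosen after the results were seen. The plucking response of aged and cKO HFSCs differed from that of young and control HFSCs in 3 gene lists by a test of the difference itself. Cell cycle genes rose less in aged and cKO cells (median log2 difference -0.868, adjusted p = 0.00169, 21 of 37 lower and 4 higher in both), epidermal differentiation genes stood higher (0.602, adjusted p = 0.0342, 14 of 27 higher and 4 lower in both) and wound genes as well (1.989, adjusted p = 0.0382, 6 of 8 higher and 1 lower in both). The adjusted p was 0.984 for each of these with an estimated correlation. In cKO cells the smaller rise lay in the unplucked arrays, since the cell cycle median of cKO against control was 0.96 without plucking and -0.07 after it. Of these unplucked arrays, the control array stood apart most from the others (median correlation 0.868). The unplucked cKO array (0.882) was hardly further from them than its plucked counterpart (0.883). The aged effect also differed from the cKO effect in cell cycle genes (-0.856, adjusted p = 0.00153; 0.773 with an estimated correlation), while 0 of 25342 genes passed that contrast (limma, 1259 at an unadjusted p under 0.05). Without regard to a test, 2822 genes were higher in both pairs of 1 effect and lower in both pairs of the other, 78 of them at least 2-fold in all 4 pairs, against 4063 that moved the same way, 85 of them at least 2-fold.

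The first pattern is the response to plucking. Of the 32 splits of the 8 HFSC arrays into 4 and 4 that could be fitted, 1, the real one, gave as many genes (127; highest other 0). The fit pairs arrays within mouse types, though, and 8 of these splits exchange labels within them, too few for a share under 0.05 (real value 127, highest other 0). Position relative to the unplucked array is argued against, since on slide 2 each plucked array lay on the other side of its unplucked partner than on slide 1. Yet 64.6% of the 2224 genes at least 2-fold apart in both pairs of slide 1 went the same way in both pairs of slide 2, and 9% the other way, against 25% each by chance. Other effects of position on the slide were not tested. A lower yield of the unplucked arrays is argued against for the cell cycle genes, because their median was 2.788 in aged mice, whose plucked array had fewer spots above background (59.18%) than the unplucked one (61.45%). An effect of plucking itself stays open beside chance.

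The second pattern is the lower level of cell cycle genes on the aged than on the young plucked HFSC array (median -0.67, 35 of 37 lower). Total epidermis and IFE, in the same slide rows, went the other way (0.558 and 0.588). Age and slide row are confounded there too, so these values cannot decide on slide row. The scaling of the arrays is argued against, since quantile normalization gave -0.669, normexp correction -0.52 and the authors' value table -0.68. More IFE cells in the aged sort are argued against as well: the 20 brightest IFE-high genes stood at -4.599 relative to the aged IFE array, a share of at most 4.13%, where 36.9% of other cells would be needed, and the sort gated on SCA1, with Ly6a at -5.11. An effect of age on the pace of cell division 3 days after plucking stays open beside slide row, and is untested, since each side has 1 array.

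The last pattern is that 26 genes were well above background on both IFE arrays and on neither total epidermis array, at least 16-fold apart, against 13 the other way. Of the 12 with a symbol, chosen here after their values were seen, 7 are named as olfactory or vomeronasal receptor genes (Olfr502, Olfr554, Olfr599, Olfr686, Olfr715, Vmn1r46 and Vmn2r99), and the others are Hdc, Mirt2, Pcdhga5, Scn7a and Tdrd6. Hdc was not confined to IFE: it stood at -0.34 and -0.38 on the young and aged IFE arrays and reached 1.05 on an HFSC array. Dilution of IFE cells in total epidermis is argued against, since the 200 IFE-high genes differed by a median of only -0.499 on the log2 scale. That is far less than the 16-fold by which the 26 genes were chosen. The difference of the 26 genes themselves (-4.25 or more, median -6.23) was set in part by that choice. Random amplification of dim transcripts is argued against by 13 genes on the IFE arrays alone, where the highest of the other array pairs (66 in all) had 1. For genomic DNA, the share of 1364 receptor genes above background was 9.97% on the young and 18.55% on the aged IFE array, against 10.56% to 21.77% on the others. That share was low where few of all spots were above background, as on young IFE (53.27%) and cKO HFSC (49.71%). It therefore cannot decide on genomic DNA. Each of the 12 genes with a symbol rests on 1 probe, whose match to other transcripts was not checked. Both IFE arrays lay in slide column 4 and both total epidermis arrays in slide column 3, so slide column cannot be told apart from population here. No biological explanation was tested.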

How the results depend on the processing

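Among the alternatives in this part, the slides taken singly, leaving out the unplucked control and cKO arrays, the fit of age in total epidermis and IFE (0 genes over its 4 arrays and 0 with the unplucked HFSC arrays), and leaving out single arrays of the population comparisons were chosen after seeing the data. Named genes kept their direction and side of the threshold in 2143 gene and setting combinations; 575 no longer passed, 23 passed anew and 7 reversed. Called lists kept their call in 133 and lost it in 47, of which 36 were with an estimated correlation, 4 with quantile scaling, 4 without the filter and 3 with normexp correction; the authors' value table ended none. The number of genes past the threshold after plucking (127) was 1121 with normexp and quantile scaling, 22 without a filter on dim probes, 691 with the strict filter, 280 with the mean of all probes, 1414 with all 12 arrays and 868 with trend and robust. The fit called 118 of the 127 genes again with normexp, 111 with quantile scaling, 123 with the authors' values, 22 without the filter, 58 with the strict filter, 115 with the mean of probes, 127 with 12 arrays and 125 with trend and robust. It was 0 without any 1 pair (0 to 0), 0 without the unplucked control and cKO arrays, 0 on slide 1 only and 0 on slide 2 only, where fewer arrays leave 1 or 2 residual degrees of freedom. A fit of all 12 arrays called 3 genes for cKO against control, 1 for control against young and 3 for aged and cKO together; the other settings called 0 in these comparisons, for aged against young and for the interaction.

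IFE against HFSC (1135 genes) gave 608 without a filter and 1765 with trend and robust, and 318 (without the aged IFE array) to 849 (without the aged HFSC array) when single arrays were left out. Total epidermis against HFSC (933) gave 1418 with normexp and quantile, 326 without a filter, 1613 with trend and robust, and 0 (without young HFSC, young total epidermis or aged total epidermis) to 880 (without aged IFE). Total epidermis against IFE (3) gave 0 with the authors' value table, 0 without a filter, 1 with the strict filter, 5 with the mean of probes, 56 with all 12 arrays, 28 with trend and robust and 0 without any 1 array (0 to 0). The number of lists past the threshold fell to 0 with an estimated correlation in each comparison with any. The reason was not tested, and the fall does not by itself show that the genes of a list vary together. The fits behind these lists left 2 to 4 residual degrees of freedom. The number of lists fell from 4 for plucking, 2 for aged against young, 1 for cKO against control, 1 for aged and cKO together, 3 for the interaction, 7 for IFE against HFSC, 9 for total epidermis against HFSC and 9 for total epidermis against IFE. It was 4 for aged against young with quantile scaling, 2 for cKO against control with quantile scaling and 2 with normexp, 2 for aged and cKO together with normexp, and 0 for cKO against control and for aged and cKO together without a filter. Rises made up 78.7% of the plucking calls and 64.7% with normexp, 67.3% with trend and robust, 62.9% with 12 arrays and 59.6% with the strict filter; higher genes made up 70.7% between single IFE arrays, 57.8% with quantile scaling, 52.8% with normexp and 51.8% with the strict filter. In 10 of the 12 single pairs, the side with more genes at least 2-fold apart turned in at least 1 setting, so these counts give no direction there. Without 1 array, the larger side also turned for IFE against HFSC (without young or aged HFSC) and for total epidermis against HFSC (without aged HFSC). The filter alone moved the median of all genes by more than 0.1: without it, by -0.14 for plucking and 0.12 for aged against young.

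In cKO against control, the median of the IFE-high genes turned from -0.136 to 0.095 without a filter, 0.066 with sets of 100 and 0.119 with sets of 400 (adjusted p between 0.56 and 0.68), and that of the HFSC-high genes from -0.078 to 0.005 with sets of 100 (adjusted p = 0.709). Cd34 turned to 0.30 for aged against young without the unplucked pair (-0.84 without the plucked pair), and to -0.22 for the interaction without the aged pair (0.87 without the cKO pair). Col17a1 turned for aged against young to 0.00 with quantile scaling (a value just under 0), -0.02 with the authors' values, -0.04 with all 12 arrays and -0.51 without the plucked pair (0.53 without the unplucked pair), and for control against young to -0.08 without the plucked pair (0.55 without the unplucked pair). With the strict filter, correlations across genes were 0.144 for aged against young (unplucked with plucked), 0.231 for control against young (0.248 with normexp) and 0.071 for aged with cKO differences after plucking. Genes at least 2-fold apart between single arrays fell with normexp and with the strict filter: aged against young, unplucked, from 7163 to 2413 and 3993, plucked from 4803 to 1051 and 2813, total epidermis from 2928 to 713 and 1326, and IFE from 2806 to 424 and 1079. For cKO against control they fell from 9233 to 4225 and 4981 unplucked (14497 without a filter), and from 5878 to 1334 and 3457 plucked. For plucking they fell from 6179 to 2232 and 3875 in young, 7908 to 3415 and 4876 in aged, 10450 to 4601 and 6954 in control and 9408 to 4568 and 5539 in cKO mice (15719 without a filter). For control against young they fell from 9824 to 3989 and 5889 unplucked, and from 5680 to 1178 and 3451 plucked. Beyond the smaller number of arrays or genes named above, the cause was not tested.

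Slide as a further term is contained in mouse type and moves nothing, so no separate fit was made. In the comparison of populations, leaving out a matched pair left no residual degrees of freedom, so single arrays were left out instead. Signal over background limits the folds: floors lay between -5.07 (control HFSC) and -3.15 (cKO HFSC) on the log2 scale, and 49.71% of spots were well above background on the cKO array, so more ratios there are lower bounds.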

Other observations

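In this part, the test of the aged effect against the cKO effect and the genes named at its end were chosen after the results were seen. BMP signalling restrains HFSC division, and its targets stood lower after plucking (median -2.04, adjusted p = 2.17e-05; 0.391 with an estimated correlation). They stood lower in cKO against control HFSCs (-0.82, adjusted p = 0.00583; 0.96 with an estimated correlation) and did not pass in aged against young HFSCs (-0.34, adjusted p = 0.475). The joint contrast of aged and cKO cells (-0.54, adjusted p = 0.0416; 0.714 with an estimated correlation) reuses the cKO arrays, and the aged effect did not differ from the cKO effect past the threshold (0.99, adjusted p = 0.172). No gene passed in the joint contrast (limma, 1490 at an unadjusted p under 0.05). All 33 splits of the 8 HFSC arrays that could be fitted gave at least that count, as any split must when the real value is 0 (highest other 0), so these splits decide nothing. Without a filter on dim probes, the list passed neither in cKO against control HFSCs (0 lists) nor in the joint contrast (0 lists).

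Mirt2 (mm9 chromosome 15, 76097239 to 76097298) stood at 1.47 and 1.5 on the young and aged IFE arrays and at -6.10 and -5.27 in total epidermis. Olfr686 (mm9 chromosome 7, 112351902 to 112351961) stood at 1.96 and 2.70 on the IFE arrays and at -6.10 and -5.27 in total epidermis.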
